A study of Mus musculus with 7 samples.

How the data were processed

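Messenger RNA was measured by RNA sequencing in cells sorted by fluorescence (FACS) from the olfactory epithelium of young mice. Per the labels, mature olfactory sensory neurons came from OMP-GFP animals at postnatal days 2, 7 and 16, and intermediate progenitor cells came from Neurog1-GFP animals at postnatal days 3, 7, 9 and 16. Per the labels' protocols, RNA was extracted with TRIzol from the sorted cells and poly(A) libraries were made with a TruSeq Stranded mRNA kit, which marks strand. The submitters' processing notes name bcl2fastq 2.18, STAR 2.6.1c and RSEM, with no version for RSEM, and the genome build mm10. The annotation release, the strand setting of the counting and the treatment of multi-mapping reads are not given in the sources used here.

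The notes give these tools no role or order. The authors deposited a table of whole-number read counts per gene, whose summary entries carry the names that STAR writes. The authors also deposited a table of TPM values, which are scaled for transcript length and to 1 fixed total per library. Both hold the same 54532 genes. The count table also has 4 entries per library that name no gene (unmapped, multi-mapping, no feature and ambiguous). They held 23.53% to 27.22% of each library's total, with multi-mapping reads at 11.86% to 13.91% and reads in no feature at 9.287% to 11.52%, and were left out of library sizes and tests. Counts on genes summed to between 24203965 and 25930727 per library. Since multi-mapping reads are kept apart from the genes, a gene with a near-identical copy can lose most of its reads in the count table. In all, 349 genes with a mean TPM of at least 1 had 0 counts in every library, 7 of them on the mitochondrial genome. Mitochondrially encoded genes, ribosomal protein genes, olfactory receptors, other gene families and genes with a pseudogene copy are uncertain for this reason. Among the 120 genes selected by the rule for named genes, 19 share exon sequence with a gene on the opposite strand and 12 with a gene on the same strand; as the strand setting is not given, reads of the former may be mixed with those of the partner.

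Groups were taken from the labels (3 mature neuron libraries, 4 progenitor libraries). Each age has 1 library per population, so the ages served as the replicates of a population. The labels do not say whether libraries came from separate animals, nor the sex of the animals. The p-values measure the spread between these libraries, which holds age as well. Population and mouse line coincide, so a difference between the populations cannot be told apart from a difference between the lines.

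The main test was edgeR 4.0.16 (quasi-likelihood fit and test, R 4.3.3) on the deposited counts, with TMM scaling, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment at 0.05. Folds are mature neuron over progenitor on the log2 scale, with a standard error from the fold and its F statistic. Expression is given as CPM, counts scaled to the library size with TMM factors, as mean ± SD over the libraries of a population. A model with population and log2 of the postnatal day gave an age slope shared by both populations, in log2 units per doubling of age, and the interaction gave the difference of slopes. These fits leave 5, 4 and 3 residual degrees of freedom. A total of 31 gene lists fixed before the data were examined were compared with the other tested genes by camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and again with an estimated one. Lists needed at least 3 tested genes. Of the listed symbols, 5 had no row in the tables. The share of counts on olfactory receptor genes and the number of receptors at 1 CPM or more were compared by exact permutation tests over the 35 splits of the 7 libraries, two-sided, whose smallest possible p is 0.0286. Shares of single libraries have 95% Wilson intervals, which cover counting error only.

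The rule for the named genes was fixed before the data were examined. For the populations it takes a fixed set of markers that includes Omp, Neurog1, Neurod1, Gap43, Gng8, Cnga2, Adcy3 and Mki67, then the 6 genes with the largest fold in each direction among those past the threshold, with a mean of at least 10 CPM in the higher population and no overlap between the populations, and up to 3 called members with the smallest p of each list. For the age slope it takes the 6 smallest p in each direction among called genes, or the 3 smallest in each direction when none is called. For the difference of slopes it takes the 3 smallest p in each direction. Receptor genes, genes named Gm with digits, Rik and -ps genes are left out of these top rules. For olfactory receptors it takes the 5 with the highest mean CPM in mature neurons and the 3 smallest p in each direction of the age slope. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

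The edgeR fits were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. Each gene was drawn independently, with the spread that the fitted trend gives for its mean level. Spread particular to a gene was not simulated, and the simulations of age held no population difference. The shares and calls below hold for that setting only. For the populations (17975 genes simulated) 28.6% of 1.5-fold, 62.3% of 2-fold and 95.2% of 4-fold changes were recovered, with 4 calls among 17462 unchanged genes tested. For the age slope (18604 genes simulated) 25.0% of changes of 1.2-fold per doubling, 80.0% of 1.5-fold and 92.5% of 2-fold were recovered, with 6 calls among 17973 unchanged genes. For the difference of slopes (18604 genes simulated) the shares were 37.0%, 68.2% and 98.4% at 1.5-fold, 2-fold and 4-fold per doubling, with 7 calls among 17925 unchanged genes. Within a population the correlation of log2 CPM between libraries reached 0.991. The chi-square of the counts of each pair of libraries of a population was at least 11.3 per degree of freedom, where counts simulated with sampling noise alone gave at most 1.02, and none was treated as a repeat of another.

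The alternatives tried were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1), with and without a minimum mean of 1 TPM, and on log2(TPM + 0.1), each library left out in turn, age as a covariate, a comparison within days 7 and 16 only, receptors left out of the library size, age on a linear scale, slopes within each population, the rotation test fry and other detection limits for receptors. Leaving out the P16 libraries of both populations, or the P3 and P7 progenitor libraries, or single libraries from the slope within progenitors, was chosen after seeing the data. Coordinates come from GENCODE release M21 for GRCm38, the assembly that mm10 names, in which 54409 of the 54532 gene identifiers were found.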

Results

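The olfactory epithelium of young mice holds sensory neurons at every stage of their formation. Sorted pools of 2 of these stages were profiled by RNA sequencing. Mature olfactory sensory neurons, marked by green fluorescent protein (GFP) in OMP-GFP mice, were collected at postnatal days 2, 7 and 16 (P2, P7, P16; 3 libraries). Intermediate progenitor cells, marked in Neurog1-GFP mice, were collected at P3, P7, P9 and P16 (4 libraries). Each library held between 24203965 and 25930727 counts on genes, and between 24494 and 26120 genes had a count above 0. The first principal component of log2 CPM held 76.0% of the variance and separated the populations. The second held 12.7%, with the P16 mature neuron library at -56.8 and the P2 mature neuron library at 36.7.

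The first comparison asked which transcripts distinguish mature neurons from progenitors. Of the gene lists fixed beforehand, 25 of 26 neuronal progenitor genes and all 29 mitosis genes were lower in mature neurons, and 24 of 27 mature neuron, 32 of 35 primary cilium and 62 of 68 oxidative phosphorylation genes were higher (edgeR, adjusted over all genes tested). As sets these lists had an adjusted p of 0.409, 0.535, 0.469, 0.339 and 0.473 with an estimated correlation. Neurog1, the proneural transcription factor that the progenitor line is named for, stood at 1.56 ± 0.495 CPM in mature neurons (SD, n = 3) and at 500 ± 228 CPM in progenitors (SD, n = 4). Its log2 fold was -8.32 (SE 0.47, edgeR quasi-likelihood adjusted p = 8.42e-06), and -7.52 on log2(TPM + 1). Its gene lies on chromosome 13 at 56250478 to 56252163 on the minus strand (GRCm38), and the 3 other tested genes within 100 kb of it were also called lower in mature neurons. Neurod1, a transcription factor of differentiating neurons, had a log2 fold of -6.16 (SE 0.31).

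In all, 5180 genes were higher and 5385 lower in mature neurons among 17975 tested (edgeR, adjusted p under 0.05), of which 2300 and 2449 differed at least 2-fold. The populations did not overlap for 11033 of the 17975 tested genes (61.4%; chance gives 5.71%). On log2(TPM + 1) the split moved from even toward progenitors, with 39.0% of 10179 called genes higher in mature neurons by limma.

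Of the mature neuron list, 24 of 27 genes rose in mature neurons and 0 fell, with a median log2 fold of 1.64 (24 and 0 adjusted over the list alone). Adcy3, the adenylyl cyclase of odorant transduction, was at 1980 ± 588 CPM in mature neurons (SD, n = 3) and 425 ± 110 CPM in progenitors (SD, n = 4; log2 fold 2.22, SE 0.26). Cnga2, a subunit of the cyclic nucleotide-gated channel, had a log2 fold of 1.41 (SE 0.17), Slc17a6, a vesicular glutamate transporter, one of 1.69 (SE 0.11), Gng13, a G protein subunit, one of 1.64 (SE 0.13) and Rtp2, a receptor-trafficking protein, one of 1.19 (SE 0.09). Omp, the gene that the mature neuron line is named for (chromosome 7, 98143359 to 98145502, minus strand), was not among the called genes. It stood at 1940 ± 441 CPM in mature neurons (SD, n = 3) and 2560 ± 639 CPM in progenitors (SD, n = 4; log2 fold -0.41, SE 0.24, edgeR adjusted p = 0.179), and it was called lower in mature neurons when the P7 progenitor library was left out (log2 fold -0.57, adjusted p = 0.0381, with a range from 0.0381 to 0.819 over its alternatives).

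**Figure D1:**
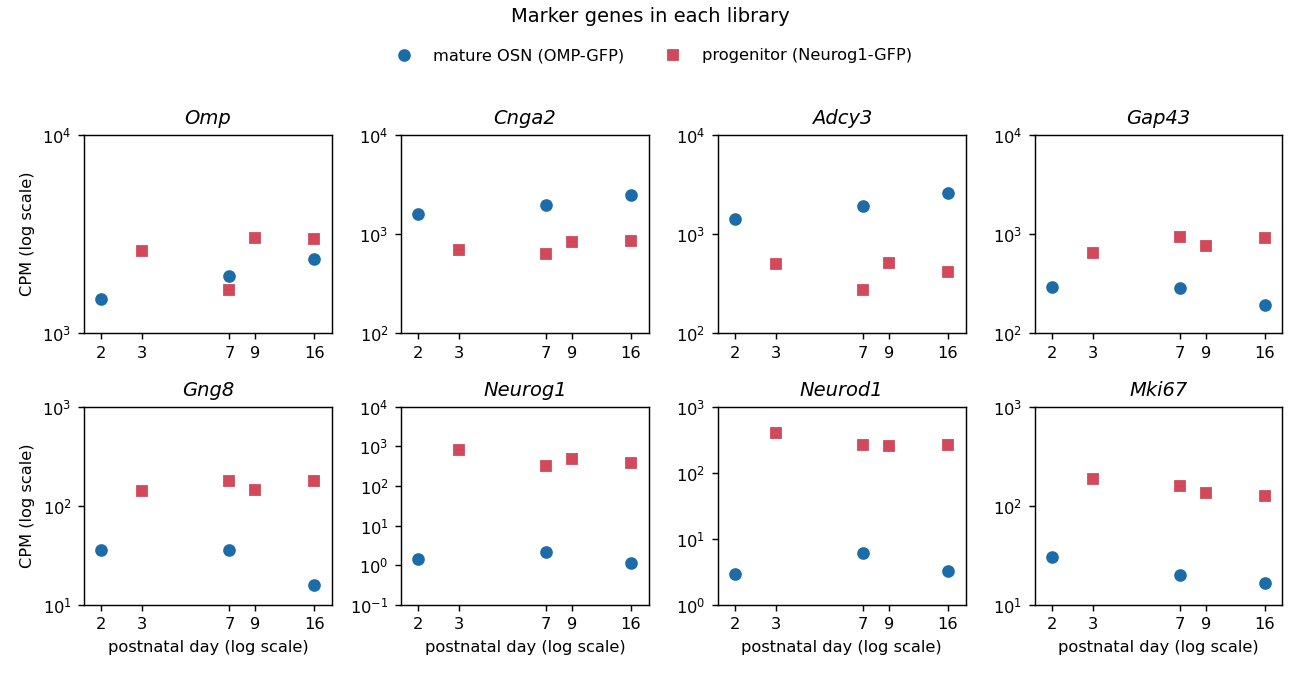
CPM (log scale) of 8 marker genes against postnatal day (log scale), 1 point per library, circles for mature neurons and squares for progenitors. Neurog1 and Neurod1 are higher in each progenitor library than in each mature neuron library, Adcy3 and Cnga2 are lower, and the values of Omp overlap.

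Most tested genes of the earlier stages were lower in mature neurons. Of 26 neuronal progenitor genes, 25 fell and 0 rose (median log2 fold -2.01; 25 adjusted over the list alone), among them Nhlh2 at -4.09 (SE 0.18) and Sox11 at -3.84 (SE 0.17), both transcription factors of early neurons. Of 23 immature neuron genes, 19 fell and 1 rose (median -1.59; 21 and 2 adjusted over the list alone). Cxcr4, a chemokine receptor, had a log2 fold of -4.13 (SE 0.17), Dpysl5, a collapsin response mediator, one of -1.99 (SE 0.13), Gng8, the G protein subunit of immature neurons, one of -2.47 (SE 0.28) and Gap43, a growth cone protein, one of -1.65 (SE 0.19). All 29 mitosis genes and 22 of 28 DNA replication genes fell and 0 rose, with medians of -2.56 and -1.24 (29 and 22 adjusted over each list alone). Mki67, a nuclear protein of dividing cells, went from 152 ± 28.2 CPM in progenitors (SD, n = 4) to 22.5 ± 7.36 CPM in mature neurons (SD, n = 3; log2 fold -2.76, SE 0.24). Ube2c had a log2 fold of -3.60 and Smc4 of -1.36 in the mitosis list, and Mcm7, a subunit of the replicative helicase, one of -1.87. In the list of cell cycle exit 11 of 18 genes fell and 2 rose (the same numbers adjusted over the list alone), with Cdkn1b, a cyclin-dependent kinase inhibitor, at -2.48, Gadd45a at -2.50 and Cdkn2c at -1.70. The camera test with the preset correlation called these 5 lists lower (adjusted p from 7.52e-10 to 0.00693). The calls were lost with estimated correlations, where the adjusted p was 0.409 for neuronal progenitor, 0.339 for immature neuron, 0.535 for mitosis, 0.690 for DNA replication and 0.473 for cell cycle exit genes. The mature neuron list, called higher at 3.89e-09, had an adjusted p = 0.469 with an estimated correlation.

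Most tested cilia and respiration genes were higher in mature neurons. Of 35 genes of primary cilium transport 32 rose and 0 fell (median log2 fold 0.54; 32 adjusted over the list alone), with Bbs7 at 1.11 (SE 0.06), Kif17 at 1.74 (SE 0.11) and Tulp3 at 0.91 (SE 0.06), which act in ciliary trafficking. Of 22 genes of respiratory motile cilia 16 rose and 4 fell (16 and 4 adjusted over the list alone), with Cfap52 at 2.10, Rsph9 at 1.04 and Rsph1 at 0.96. That list was fixed as markers of other cells that a sort could hold. Of 68 nuclear genes of oxidative phosphorylation 62 rose and 1 fell (62 and 1 adjusted over the list alone), among them the complex I subunits Ndufs1 at 0.76 and Ndufa13 at 1.25. Ndufs5, another subunit, had a log2 fold of 4.41 but only 4.29 ± 0.206 CPM in mature neurons (SD, n = 3), and its fold on log2(TPM + 0.1) was 1.48. Of the 13 mitochondrially encoded genes of the list 7 were tested, and 6 of these rose (7 adjusted over the list alone). Among them were mt-Cytb at 0.64 (SE 0.15), mt-Nd2 at 0.52 and mt-Nd4 at 0.54. As 7 genes of the mitochondrial genome had 0 counts despite a mean TPM of at least 1, the counts miss part of the mitochondrial signal. With only the P7 and P16 libraries and age as a block the calls on mt-Nd2 (0.33, edgeR adjusted p = 0.0612) and mt-Nd4 (0.37, 0.0584) were lost, the highest values over their alternatives, whose lowest were 0.000109 and 7.4e-05. With the preset correlation camera called these 4 lists higher (adjusted p from 4.5e-14 to 0.0149), and with estimated correlations the adjusted p was 0.339, 0.339, 0.473 and 0.644, in the order given.

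In the list of olfactory receptor choice and chromatin factors 30 of 42 genes fell in mature neurons and 6 rose (the same adjusted over the list alone; median log2 fold -0.59). Smchd1, a chromatin protein, went from 449 ± 52.4 CPM in progenitors (SD, n = 4) to 106 ± 10.1 CPM (SD, n = 3), a log2 fold of -2.09 (SE 0.12), which was -3.49 on log2(TPM + 0.1). Hdac2, a histone deacetylase, had a log2 fold of -1.94 (SE 0.12) and Ehmt1, a histone H3 methyltransferase, one of -1.62 (SE 0.07). Of 82 cytosolic ribosomal protein genes 58 fell and 6 rose (61 and 6 adjusted over the list alone), with Rpl10 at -1.26, and of 23 genes of cholesterol synthesis 11 fell and 2 rose (the same adjusted over the list alone). Mvd, an enzyme of that pathway, had a log2 fold of -1.61, while Ebp had 0.59. Camera called these 3 lists lower with the preset correlation (adjusted p = 2.54e-05, 1.97e-06 and 0.0346), and the adjusted p was 0.339, 0.473 and 0.719 with an estimated correlation. The call on cholesterol synthesis was also lost without the P16 mature neuron library (0.0952) and without the P3 progenitor library (0.0600), and on log2(TPM + 1) it was 0.0699, within a range from 0.0063 to 0.719 over its alternatives. By fry it was 0.15.

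Several lists had members moving both ways and were not called by camera. The rotation test fry, which asks whether the genes of a list move on balance one way, called presynaptic genes higher (adjusted p = 0.00584) and unfolded protein response (0.0291), Wnt (0.0437) and Notch genes (0.0459) lower in mature neurons. In the axon guidance list 19 genes rose and 17 fell of 49 (the same adjusted over the list alone; camera adjusted p = 0.884), with a median log2 fold of 0.01 and a mean of -0.19. Unc5b, a netrin receptor, had a log2 fold of 1.31 and Robo3, a receptor of the Slit pathway, one of -4.61. That of Robo3 was -3.58 on log2(TPM + 0.1) and -1.7 on log2(TPM + 1). In the presynaptic list 11 rose and 6 fell of 27 (12 and 6 adjusted over the list alone; 0.209), with Syt1, the calcium sensor of vesicle release, at 1.29 and Rab3a at 0.88. In the Notch list 4 rose and 11 fell of 22 (5 and 11 adjusted over the list alone; 0.209), with Mfng at -5.62, Lfng at -4.24 (-3.25 on log2(TPM + 1)) and Hes6 at -2.82. In the Wnt list 2 rose and 17 fell of 42 (2 and 15 adjusted over the list alone, camera adjusted p = 0.0811). Wnt3 had a log2 fold of -3.55 (-2.35 on log2(TPM + 0.1) and -0.65 on log2(TPM + 1)), Lrp5 one of -1.54 and Axin1 one of -0.49. In the unfolded protein response 4 rose and 5 fell of 20 (3 and 5 adjusted over the list alone; 0.387), with Dnajb9 at 1.16, Pdia4 at -0.59 and Manf at -0.48. In the heat shock list 5 rose and 1 fell of 15 (the same adjusted over the list alone; 0.0885), with Hspa8 at 1.08, Dnajb4 at 0.42 and Dnaja1 at 0.41, whose call was lost by limma on log2(TPM + 1) (0.21, adjusted p = 0.0872, with a range from 0.00135 to 0.105 over its alternatives). In the immediate early list 2 rose and 5 fell of 25 (2 and 4 adjusted over the list alone; 0.846), with Ier5 at -1.05, Nr4a3 at -0.85 and Btg2 at -0.43. None of the 5 tested sex-linked genes was called (0.529).

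**Figure D2:**
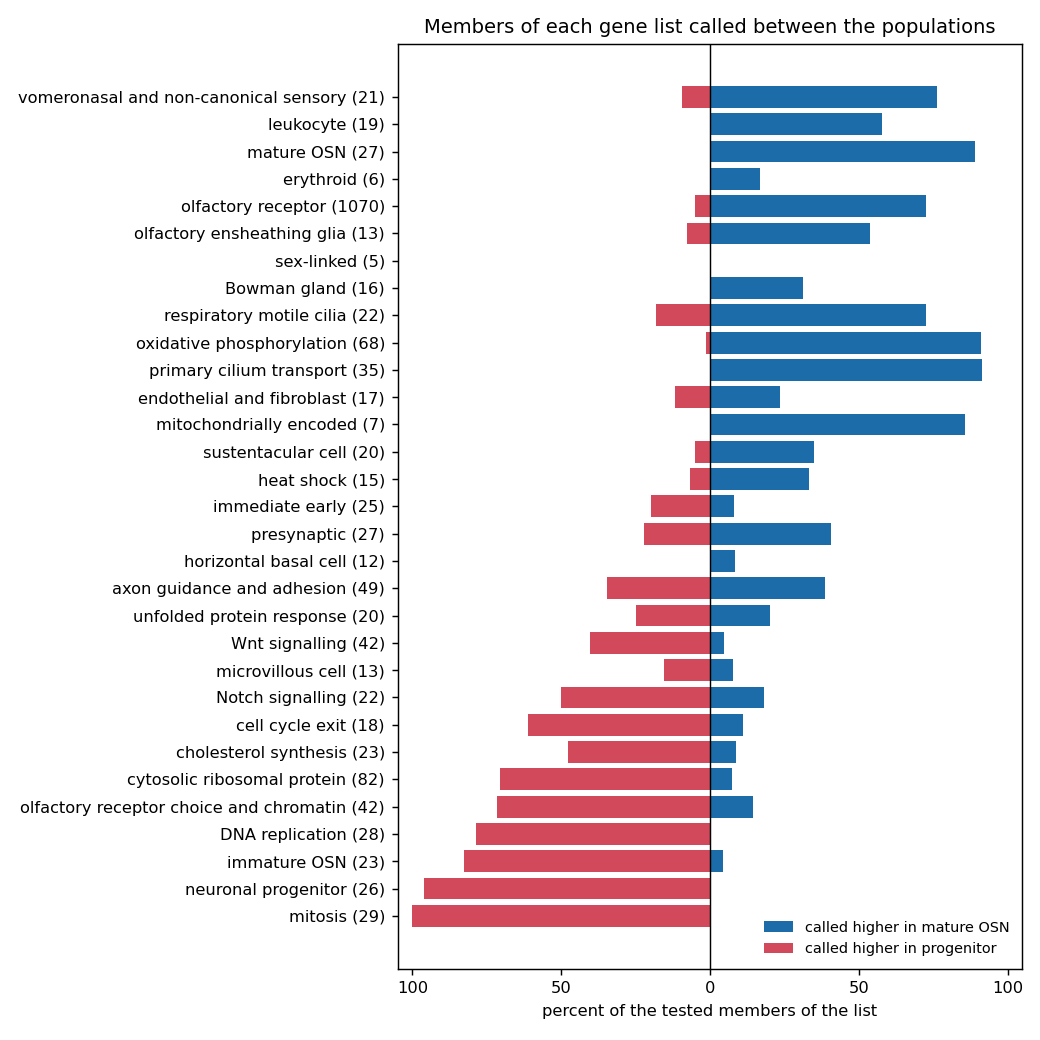
Percent of the tested members of each of 31 gene lists called higher in mature neurons (bars to the right) or in progenitors (bars to the left), with the number tested in brackets. All 29 mitosis genes lie on the progenitor side, and 32 of 35 primary cilium genes on the mature neuron side.

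Among the genes with the largest folds, Cxcl14, a chemokine and neighbour of Neurog1 (chromosome 13, 56288643 to 56296551, minus strand), stood at 61.1 ± 37.2 CPM in progenitors (SD, n = 4) and 0.709 ± 0.218 CPM in mature neurons (SD, n = 3), a log2 fold of -6.42 (SE 0.57, edgeR adjusted p = 4.68e-05). Ooep had a log2 fold of -6.27 (SE 0.26) and Vcp-rs, a copy related to Vcp, one of -6.31 (SE 0.14). In the other direction stood Rps3a3 at 6.88, Tpm3-rs7 at 5.38, Rpl26 at 5.35, Tmem59l at 4.80, Dmkn at 4.53 and Car6, a secreted carbonic anhydrase, at 4.02. Rps3a3 and Vcp-rs are annotated as processed pseudogenes, and Tpm3-rs7 is named as a related sequence of another gene. Reads of these and of Rpl26 may be shared with near-identical copies, so their folds are uncertain. On log2(TPM + 0.1) the fold of Rpl26 was 2.19, that of Tpm3-rs7 3.57, that of Vcp-rs -4.76 and that of Ooep -5.67. Cxcl14 stood at 116 CPM in the P3 progenitors and between 36.7 and 52.9 CPM in the later ones. Its fold was -5.91 without the P3 library (edgeR adjusted p = 2.43e-05) and -5.53 with only P7 and P16 and age as a block (1.75e-05, with a range from 1.94e-46 to 0.000467 over its alternatives). Car6 stood at 17.4, 2.6 and 15.1 CPM in mature neurons at P2, P7 and P16. Its fold was 3.08 with only P7 and P16 and age as a block (edgeR adjusted p = 0.0158, the highest over its alternatives, whose lowest was 1.12e-08) and 5.02 without the P3 and P7 progenitor libraries (0.0133). On log2(TPM + 1), which lowers the folds of weakly expressed genes, those of Cxcl14, Ooep, Tmem59l and Car6 were -5.01, -3.72, 3.89 and 2.55.

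Genes of the lists fixed for other cell types, some of them other sensory neurons, had transcripts in both populations. The summed CPM of 22 sustentacular (supporting) cell genes ranged from 4760 to 5580 in mature neurons and from 2760 to 4290 in progenitors. Of 20 tested members 7 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.0885), with Sult1d1, a sulfotransferase, at 1540 ± 240 and 640 ± 88.2 CPM (SD, n = 3 and n = 4; log2 fold 1.27) and Gstm2 at a log2 fold of 0.69. Leukocyte genes rose for 11 of 19 and fell for 0 (the same adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.719 with an estimated correlation), with C1qb at 2.54, Ccl3 at 1.98 and Ccl4 at 2.08. Their summed CPM was 244 in the P16 mature neuron library and between 20.5 and 53.3 in the other 6, and the list was not called without that library (0.101), by fry (0.123) or without the P3 and P7 progenitor libraries (a choice made after seeing the data), within a range from 0.00144 to 0.719 over its alternatives. Of 13 genes of olfactory ensheathing glia 7 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.287), with Fabp7 at 17.1 CPM in mature neurons and 3.76 CPM in progenitors and Mbp at a log2 fold of -1.75. In the Bowman gland list 5 of 16 rose (2 adjusted over the list alone; 0.302), with Aqp4, a water channel, at 1.27, Bpifb9a at 3.54 and Sox10 at 1.28. In the erythroid list 1 of 6 rose (0 adjusted over the list alone; 0.668), Hba-a2 at 2.35. In the endothelial and fibroblast list 4 rose and 2 fell of 17 (2 and 1 adjusted over the list alone; 0.846), with Pdgfrb at 1.68, Dcn at 0.78 and Fbln1 at -2.66. In the microvillous list 1 rose and 2 fell of 13 (the same adjusted over the list alone; 0.846), with Pou2f3 at 1.13, Coch at -1.86 and Itpr3 at -0.71. Of 12 horizontal basal cell genes only Dst was called (0.47; 1 adjusted over the list alone; 0.884), and limma on log2(TPM + 1) did not call it (0.24, adjusted p = 0.101, with a range from 0.000396 to 0.117 over its alternatives). In the list of vomeronasal and non-canonical sensory neurons 16 of 21 genes rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 3.95e-05, and adjusted p = 0.339 with an estimated correlation). The trace amine-associated receptors Taar2, Taar7d and Taar7e had log2 folds of 2.71, 2.63 and 2.56. On log2(TPM + 1) the folds of C1qb, Ccl3, Ccl4, Pdgfrb, Fbln1 and Taar7e were 1.60, 1.14, 1.05, 0.76, -1.73 and 1.85, each still called. Some of the single-gene calls were lost, or their folds moved, without single libraries. Without the P16 mature neuron library the fold of Bpifb9a was 1.58 (edgeR adjusted p = 0.0213, from 0.00443 to 0.0606 over the alternatives), that of C1qb 1.58 (0.00705, from 5.11e-05 to 0.0736) and that of Coch -2.71 (3.78e-05, from 1.07e-05 to 0.0329). Without it the calls on Hba-a2 (0.77, edgeR adjusted p = 0.247) and Sox10 (0.68, 0.131) were lost. Without the P2 mature neuron library those on Aqp4 (0.90, edgeR adjusted p = 0.0535), Gstm2 (0.58, 0.0508) and Itpr3 (-0.55, 0.0605) were lost. The call on Itpr3 was also lost without the P7 mature neuron library (-0.73, 0.0501). That on Hba-a2 was lost without the P3 (2.06, 0.0769), P7 (2.56, 0.0550) or P9 progenitor library (2.15, 0.0827). That on Sox10 was lost without the P3 (1.11, 0.0743), P9 (1.23, 0.0723) or P16 progenitor library (1.31, 0.0583). Over all their alternatives the adjusted p ranged from 0.00285 to 0.509 for Hba-a2, from 0.00998 to 0.156 for Sox10, from 5.82e-05 to 0.0797 for Aqp4, from 0.00138 to 0.105 for Gstm2 and from 0.00576 to 0.211 for Itpr3. By limma on log2(TPM + 1) the calls on Hba-a2 (0.75, adjusted p = 0.485), Sox10 (0.34, 0.0954), Aqp4 (0.99, 0.0634) and Gstm2 (0.49, 0.0802) were lost. With only P7 and P16 and age as a block those on Sox10 (1.13, edgeR adjusted p = 0.114) and Itpr3 (-0.47, 0.211) were lost. Without the P3 and P7 progenitor libraries, where fewer libraries entered the test, these calls, that on Dst and those on C1qb (edgeR adjusted p = 0.0736), Ccl3 (1.67, 0.0594), Ccl4 (1.85, 0.0549), Dcn (0.73, 0.0522) and Bpifb9a (4.09, 0.0606) were lost, though none of these folds, that of C1qb included, moved by more than 1.5-fold. For the last 5 these were the highest values over their alternatives, whose lowest were 5.11e-05, 0.00109, 0.000851, 5.39e-05 and 0.00443.

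Olfactory receptor genes took about 2-fold more of the counts in mature neurons. The share was 1.575 ± 0.047% in mature neurons (SD, n = 3) and 0.7575 ± 0.0732% in progenitors (SD, n = 4; exact permutation p = 0.0286, the smallest that 35 splits allow). With 1 library left out the difference stayed between 0.782 and 0.84 percentage points, with an exact permutation p of 0.0667 or 0.1, the smallest those splits allow. Single libraries ranged from 0.6503% (95% Wilson interval 0.6472 to 0.6534%) in the P3 progenitors to 1.623% (1.618 to 1.628%) in the P2 mature neurons. Of 1070 tested receptors 777 rose in mature neurons and 55 fell, with a median log2 fold of 1.21 (800 and 56 adjusted over the list alone; camera adjusted p = 1.13e-17, and adjusted p = 0.339 with an estimated correlation). The receptors with the smallest p were Olfr969 at 2.06 (SE 0.07), Olfr1046 at 7.84 (SE 0.28) and Olfr849 at 1.93 (SE 0.09). The fold of Olfr1046 was 7.20 on log2(TPM + 0.1) and 5.17 on log2(TPM + 1). The number of receptors at 1 CPM or more did not differ beyond the spread, with 1002 ± 16.3 of 1107 in mature neurons (SD, n = 3) and 997.8 ± 12.2 in progenitors (SD, n = 4; exact permutation p = 0.714). Counted at 10 or more reads, progenitors had more receptors by a mean of 20.3 (signed difference -20.3, exact permutation p = 0.0286), and at 1 CPM the difference of 3.92 turned to -1.75 without the P2 mature neuron library and to -1.33 without the P3 progenitor library. The receptors with the highest mean in mature neurons were Olfr536 at 239 ± 190 CPM, Olfr1507 at 149 ± 92.6 CPM, Olfr309 at 112 ± 3.86 CPM, Olfr728 at 111 ± 88.6 CPM and Olfr523 at 102 ± 8.13 CPM (SD, n = 3 each). Olfr309 and Olfr523 rose in mature neurons (log2 folds 1.96 and 1.78). Olfr728 had a log2 fold of 1.51, whose call was lost without the P16 mature neuron library (0.62, edgeR adjusted p = 0.0613) and without the P3 (1.39, 0.0623), P7 (1.43, 0.0616) or P9 progenitor library (1.5, 0.0543) and by limma on log2(TPM + 1) (1.08, 0.0788), within a range from 0.000529 to 0.18 over its alternatives. Olfr536 and Olfr1507 were not called (0.43 and 0.52, edgeR adjusted p = 0.45 and 0.421), and the fold of Olfr536 was -0.45 without the P16 mature neuron library. With only the P7 and P16 libraries of both populations and age as a block both were called higher in mature neurons (0.63 and 1.67, edgeR adjusted p = 0.0359 and 3.62e-05, the lowest over their alternatives, whose highest were 0.926 and 0.991). Receptors are a large family, so reads shared between members make single values uncertain.

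**Figure D3:**
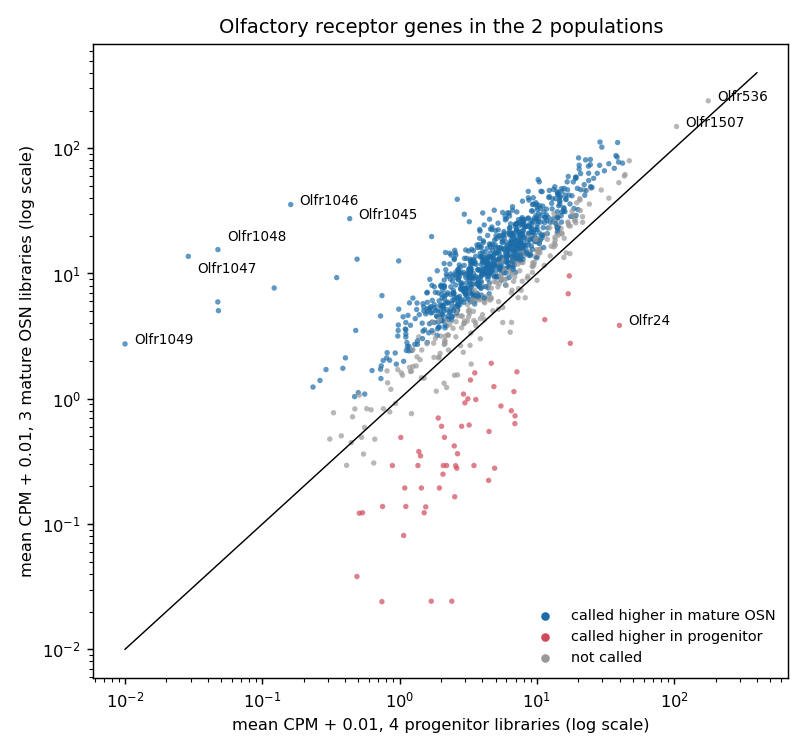
Mean CPM plus 0.01 of each tested olfactory receptor gene in the 3 mature neuron libraries against the 4 progenitor libraries (both axes log scale), 1 point per gene, coloured by the edgeR call. Most of the 1070 points lie above the line of equality, and Olfr1045 to Olfr1049 stand far to the left.

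The second comparison asked which transcripts changed over postnatal days 2 to 16 in both populations alike. Of the lists that camera called lower with age, those of mitosis and DNA replication had the lowest median slopes, and of those called higher, erythroid and leukocyte genes had the highest. Each of these 4 lists had an adjusted p = 0.429 with an estimated correlation, and leukocyte genes were called in the opposite direction without the P16 libraries of both populations (camera adjusted p = 0.0374). No single gene passed the threshold. Of 18604 genes tested 0 were called (edgeR, smallest adjusted p 0.0532), while 3849 had an unadjusted p under 0.05, where 930 are expected by chance. The DESeq2 Wald test called 651 rising and 873 falling genes, edgeR with age in days on a linear scale called 474 and 711, and edgeR without the P7 mature neuron library called 367 and 619. The genes nearest the threshold on the falling side were Mki67 with a slope of -0.28 log2 units per doubling of age, Thbs1, a matrix glycoprotein, with -0.53, and Plppr5 with -0.88. On the rising side they were Pmepa1 with 0.32, Kcnh4, a potassium channel, with 0.23, and F8, coagulation factor VIII, with 0.34. All 6 missed the threshold at an edgeR adjusted p of 0.0532 and passed it with DESeq2, with age in days, with no low-count filter and without the P7 mature neuron library (from 0.00581 to 0.0143). Over all alternatives their adjusted p ranged from 4.73e-10 for Thbs1 to 0.603.

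As sets, 12 lists fell with age and 8 rose by camera with the preset correlation, and none of these calls held with estimated correlations. Mitosis genes had a median slope of -0.35 (camera adjusted p = 2.24e-21) and DNA replication genes one of -0.26 (1.65e-15), and each had an adjusted p = 0.429 with an estimated correlation. Adjusted over the list alone, 28 of 29 and 23 of 28 genes fell. Without the P3 progenitor library the medians were -0.33 and -0.26 and camera still called both lists. Within progenitors, however, the fall lay mainly between P3 and P7. The median slopes fitted there went from -0.31 to -0.10 for mitosis and from -0.27 to -0.14 for DNA replication genes without the P3 library. That library also had the lowest Ddx3y (0.149 CPM), a Y-linked gene chosen after its values were seen. Within the mature neuron libraries the median slopes of the mitosis and DNA replication lists were -0.40 and -0.29. The summed CPM of the mitosis genes was low there, at 298, 227 and 153 at P2, P7 and P16, against 1040 to 1680 in progenitors. Which of the sorted cells held these transcripts was not tested, so the slopes need not be a change within mature neurons. The self-contained test fry also called both (adjusted p = 0.0443) and none of the other lists. Neuronal progenitor genes had a median slope of -0.15 (camera adjusted p = 2.76e-06; 4 fell adjusted over the list alone) and Wnt, Notch and immediate early genes had medians of -0.17, -0.18 and -0.20 (0.000469, 0.00524 and 9.32e-05; 10, 1 and 10 fell and 0, 0 and 1 rose adjusted over each list alone). Mature neuron genes had a median slope of 0.13 (7.83e-05; 6 rose adjusted over the list alone) and genes of primary cilium transport one of 0.04 (0.000158; 0 adjusted over the list alone). Each of these 6 lists had an adjusted p = 0.429 with an estimated correlation. Without the P3 progenitor library the median slope was -0.08 for neuronal progenitor, -0.07 for Wnt and 0.21 for mature neuron genes, and without the P16 mature neuron library it was 0.05 for the last. Cholesterol synthesis (-0.12), ribosomal protein (-0.05), cell cycle exit (-0.14), oxidative phosphorylation (-0.05) and immature neuron genes (-0.07) were called lower by small medians (camera adjusted p from 1.46e-05 to 0.0356), with an adjusted p of 0.429, 0.429, 0.429, 0.585 and 0.597 with an estimated correlation. Adjusted over the list alone, 0, 0, 3, 0 and 6 of their genes fell and 1 immature neuron gene rose. Without the P3 progenitor library the calls on Notch (0.360), cell cycle exit (0.270) and ribosomal protein genes (0.137) were lost. Without the P16 mature neuron library those on cholesterol synthesis (0.119) and immature neuron genes (0.879) were lost. The last was also lost without the P2 mature neuron (0.0647), P7 progenitor (0.0625) or P9 progenitor library (0.0615), and on log2(TPM + 1) those on immature neuron (0.0999) and Notch genes (0.0536) were lost. Over their alternatives the adjusted p ranged from 3.24e-06 to 0.429 for Notch, from 0.00464 to 0.429 for cell cycle exit, from 4.63e-08 to 0.429 for ribosomal protein, from 3.94e-07 to 0.429 for cholesterol synthesis and from 0.00907 to 0.962 for immature neuron genes.

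Markers of other cells moved with age in the same libraries. Erythroid genes had a median slope of 1.08 (camera adjusted p = 3.74e-09; 9 of 9 rose adjusted over the list alone) and leukocyte genes one of 0.46 (2.76e-06; 10 of 19). Ensheathing glia and Bowman gland genes had medians of 0.39 and 0.42 (0.00449 and 0.00698; 7 rose and 1 fell, and 4 rose and 1 fell, adjusted over each list alone), and each of these 4 lists had an adjusted p = 0.429 with an estimated correlation. Sustentacular genes had a median of -0.18 (0.00253; 2 rose and 5 fell adjusted over the list alone; adjusted p = 0.439 with an estimated correlation). Presynaptic and heat shock genes had medians of 0.04 and 0.05 (0.0308 and 0.00629; adjusted p = 0.429 each with an estimated correlation; 1 and 0 rose adjusted over each list alone). Without the P16 mature neuron library the calls on leukocyte (0.166), Bowman gland (0.398) and heat shock genes (0.464) were lost. That on presynaptic genes was lost without the P2 mature neuron (0.0962) or P3 progenitor library (0.136). Over their alternatives the adjusted p ranged from 1.78e-09 to 0.429 for leukocyte, from 0.000383 to 0.429 for Bowman gland, from 0.000522 to 0.464 for heat shock and from 0.00401 to 0.429 for presynaptic genes. The highest sums of erythroid, leukocyte and Bowman gland genes stood in the P16 mature neuron library, where erythroid genes reached 317 CPM against 35.3 and 42.3 CPM at P2 and P7. In progenitors they were at 17.6, 69.4, 47.4 and 132 CPM from P3 to P16. Without the P16 libraries of both populations, an alternative chosen after seeing the data, the mitosis (camera adjusted p = 6.24e-34), DNA replication (1.26e-18), erythroid (0.00475) and ensheathing glia lists (0.00475) were called in the same direction, as were those of neuronal progenitor, cell cycle exit, primary cilium transport, Notch, presynaptic, oxidative phosphorylation and ribosomal protein genes. Leukocyte genes were then called lower with age (0.0374), and the lists of mature neuron (0.0569), Wnt (0.0569), cholesterol synthesis (0.128), immediate early (0.298), heat shock (0.298), Bowman gland (0.127), immature neuron (0.962) and sustentacular genes (0.962) were not called.

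**Figure D4:**
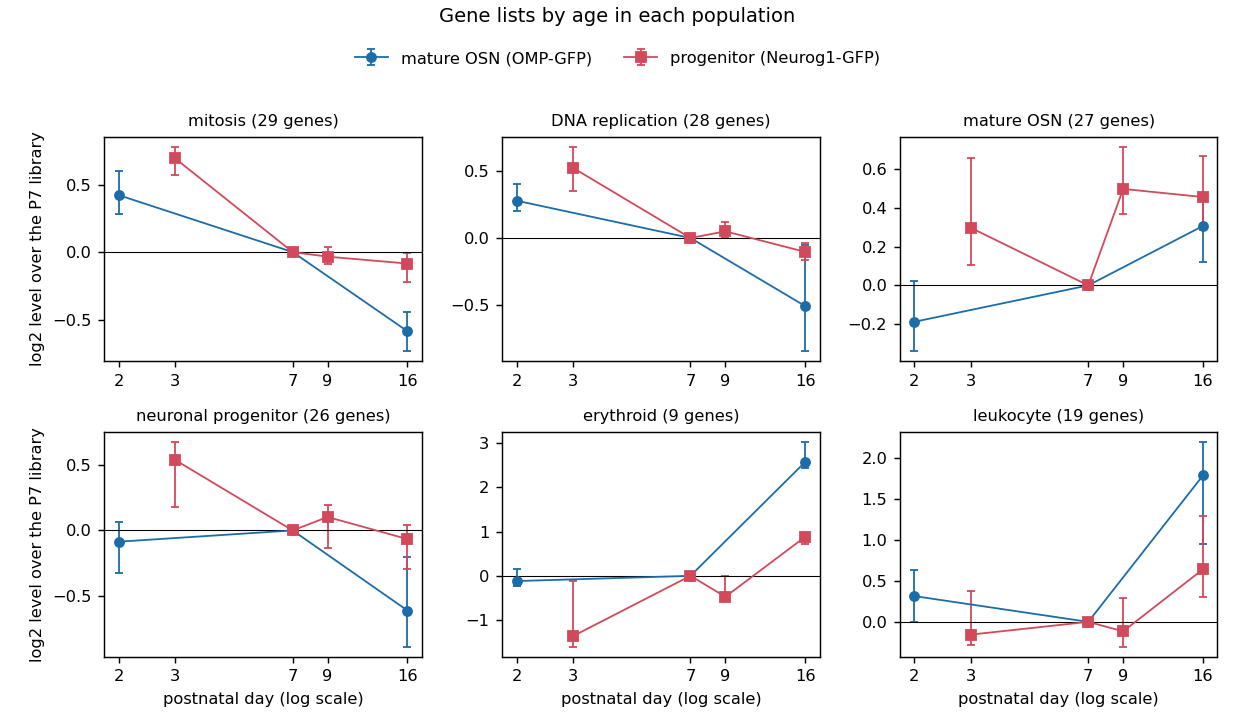
Median over the members of 6 gene lists of the log2 level relative to the P7 library of the same population, against postnatal day (log scale), with bars from the lower to the upper quartile of the members. The mitosis median falls from 0.422 at P2 to -0.587 at P16 in mature neurons and in progenitors it stands at 0.695 at P3 and at -0.034 and -0.085 at P9 and P16, close to the P7 level, and the erythroid median reaches 2.573 in the P16 mature neurons.

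Olfactory receptors as a list had no common age slope (median -0.03, camera adjusted p = 0.661), yet 91 rose and 2 fell adjusted over the list alone, of 1072 tested, and the mean slope was 0.01. The smallest p among rising receptors belonged to Olfr729 (slope 0.50), Olfr1193 (0.81) and Olfr539 (0.40), and among falling ones to Olfr631 (-0.61), Olfr1160 (-0.30) and Olfr1058 (-0.49), none of them called over all genes (edgeR adjusted p from 0.0532 to 0.0987). Without the P7 mature neuron library all of these but Olfr1160 were called, with an edgeR adjusted p from 0.00956 for Olfr1193 to 0.0378 for Olfr631, and over all alternatives it ranged from 2.81e-08 for Olfr729 to 0.79 for Olfr1058. Olfr536 had a slope of 0.56 (adjusted p = 0.0581). The 10 most abundant receptors took 5.73%, 6.34% and 10.8% of receptor CPM in mature neurons at P2, P7 and P16, and 8.52%, 6.74%, 10.4% and 9.33% in progenitors at P3, P7, P9 and P16.

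The third comparison asked whether the age slope differed between the populations. By camera with the preset correlation, the lists of olfactory receptor, sex-linked, cholesterol synthesis and immature neuron genes had a lower slope in mature neurons, and those of Notch, ribosomal protein and chromatin genes a higher one. Each had an adjusted p = 0.971 with an estimated correlation and 0.99 by fry. The median log2(CPM + 1) of the sex-linked genes was 0.267, 2.72, 4.9 and 4.74 in progenitors from P3 to P16 and between 5.02 and 5.22 in mature neurons. The labels do not give the sex of the animals in each pool, so for this list a slope with age cannot be told apart from a difference in sex between the pools. The Y-linked gene Ddx3y, chosen after its values were seen, stood at 0.149 CPM in the P3 progenitors and at 30.1 and 26.9 CPM in those of P9 and P16. No single gene was called among 18604 tested (edgeR, smallest adjusted p 0.815), 1098 had an unadjusted p under 0.05 where 930 are expected by chance, and the DESeq2 Wald test called 8 with a higher and 2 with a lower slope in mature neurons. Bmf, Rps3a1 and Slc43a2 were among the former. The smallest p belonged to Bmf, Rps3a1 and Slc43a2, with slopes higher in mature neurons by 0.75, 0.66 and 0.32 log2 units per doubling, and to Reep5, Lipo3 and Col2a1, with differences of -0.41, -0.52 and -0.45. Camera with the preset correlation called these 7 lists. Among the lower slopes were those of olfactory receptors (median difference -0.20, camera adjusted p = 3.49e-08), sex-linked (-2.43, 0.00588), cholesterol synthesis (-0.10, 0.01) and immature neuron genes (-0.13, 0.032). Those of Notch (0.13, 0.000408), ribosomal protein (0.05, 0.0329) and chromatin genes (0.03, 0.0329) were higher. Adjusted over the list alone, 4 sex-linked genes had a lower and 2 Notch genes and 1 ribosomal protein gene a higher slope in mature neurons, and 0 genes passed in the other 4 lists. Each call depended on single libraries. It was lost without the P3 progenitor library for receptors (0.313), immature neuron (0.305), chromatin (0.172) and ribosomal protein genes (0.270). Without the P2 mature neuron library it was lost for Notch (0.946), sex-linked (0.0623), chromatin (0.719) and ribosomal protein genes (0.0673). Without the P7 mature neuron library it was lost for chromatin genes (0.1) and without the P9 progenitor library for ribosomal protein genes (0.0557). Without the P16 progenitor library it was lost for immature neuron (0.211) and cholesterol synthesis genes (0.195). Without the P16 mature neuron library it was lost for immature neuron (0.276) and ribosomal protein genes (0.245), and cholesterol synthesis genes were called in the opposite direction (0.0451). On log2(TPM + 1) it was lost for immature neuron (0.13) and chromatin genes (0.286). Over the alternatives the adjusted p of each list reached 0.99, from a lowest of 5.31e-11 for receptors, 1.03e-09 for sex-linked, 4.12e-11 for cholesterol synthesis, 6.52e-07 for immature neuron, 2.08e-06 for Notch, 0.00109 for ribosomal protein and 0.000483 for chromatin genes.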

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

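The tests of the splits and of shared reads and of the DNA around Omp were planned before their results were seen, and the tests of Omp and the other mature neuron markers, of neighbouring receptors, of the reporter allele and of the genes around Neurog1 were chosen after the result was seen.

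Within the 4 progenitor libraries 122 measures were examined for a library far from the others, and 12 stood out, where chance gives about 1 in 20; 11 are given here. In 9 of them the P3 library was highest: Neurod1 at 402 CPM, Mfng at 183 CPM, Rrm1 at 118 CPM, Gadd45a at 118 CPM, Lfng at 55.4 CPM, Bmf at 38.4 CPM, Rpl10 at 25.5 CPM, Fbln1 at 12.1 CPM and Cdkn2c at 9.3 CPM. The P7 library was highest for Robo3 at 7.43 CPM, and the P16 library for C1qb at 1.65 CPM.

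The age slope was called different between the populations, by camera with the preset correlation on the difference itself, for the lists of olfactory receptors (camera adjusted p = 3.49e-08), Notch signalling (0.000408), sex-linked genes (0.00588), cholesterol synthesis (0.01), immature neurons (0.032), receptor choice and chromatin (0.0329) and ribosomal proteins (0.0329). Each had an adjusted p = 0.971 with an estimated correlation and 0.99 by fry, and each call was lost when some single library was left out, such as the P3 progenitors for receptors (0.313), the P2 mature neurons for Notch (0.946), sex-linked (0.0623), chromatin (0.719) and ribosomal protein genes (0.0673), and the P16 progenitors for cholesterol synthesis (0.195) and immature neuron genes (0.211). The sex of the animals in each pool is not in the labels, so for the sex-linked list age and sex cannot be told apart. The Y-linked gene Ddx3y, chosen after its values were seen, stood at 0.149 CPM in the P3 progenitors, 6.28 CPM at P7, 30.1 CPM at P9 and 26.9 CPM at P16, and between 30.5 and 35.1 CPM in the mature neurons.

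A signal stood in the TPM table outside the count comparisons. The mitochondrial gene mt-Atp8 had 0 counts in every library and a mean of 11000 TPM in mature neurons.

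By rank among the splits of the libraries, chance is argued against for the number of genes called between the populations. Of the 35 splits of the 7 libraries 1, the real one, called as many as 10565, and the highest other split called 0. This is the smallest share that 35 splits allow (0.0286). Every other split mixed the populations, which puts their difference into the spread within the groups. The 0 calls there thus do not show how many genes chance alone would give. For the number of lists that camera called with the preset correlation the splits cannot decide, and chance is not excluded. There 17 of the 35 splits called 16 lists or more and the highest other split called 23. Each split still held the populations in unequal shares, so the population difference could lead to calls in all of them. For age, 100 of the 144 orders of the ages within the populations were drawn and 44 were not run; 3 of the 100 gave as many genes at an unadjusted p under 0.05 as the real 3849; the others gave 3885, with only P7 and P9 of the progenitors exchanged, and 4513, which was the reverse of that order. At an edgeR adjusted p under 0.05 they called 120 and 1448 genes where the real order called 0, so the high counts stand along the same axis of the samples in either direction. As many lists as the real 20 were called in 2 of the 100 orders, with a highest other of 20. By these 2 counts few of the drawn orders reached the real one. Chance is not excluded by them, since 44 orders were not run and orders in the reverse direction also scored high. By the number of genes called it cannot be excluded either. At the adjusted threshold, where the real order called 0 genes, 14 of the 99 other orders called 1 or more.

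Mature neuron transcripts stood at a substantial level in the progenitor libraries, and Omp did not differ beyond the spread (log2 fold -0.41, edgeR adjusted p = 0.179). Over the 23 mature neuron markers other than Omp with at least 100 CPM, the ratio of progenitor to mature neuron CPM had a median of 0.321 and went from 0.0938 for S100a5 to 0.958 for Calb2. Mature neuron RNA carried into the progenitor sort in 1 share would give them 1 ratio, but 21 of the 22 other markers had a lowest library ratio above the highest of S100a5 (0.119), which argues against such carry-over as the whole source. For Omp itself the ratio was 1.33, above the highest of the others at P16 (1.26 against 1.25) but below it at P7 (0.849 against 0.952). That comparison could not decide, since carry-over in 1 share does not account for the highest markers either. Such a share could be no larger than the ratio of S100a5, which was 0.0728 at P7 and 0.0656 at P16. If mature neurons hold the same Omp level in both lines, this argues against carried RNA as the main source of Omp in progenitors. Omp reads lowered in the mature neuron line alone would lift that limit. The values therefore cannot decide while the explanation given next is open, and carried RNA stays open. A candidate explanation is also a reporter allele that takes the place of Omp reads in the mature neuron line, but 0 entries of the tables name a reporter sequence, and this stays open with an untested biological difference in the maturity of the sorted cells.

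A set of genes differed strongly between the populations, which coincide with the mouse lines. At an absolute log2 fold of at least 5, 155 called genes stood apart, 62 of them annotated as pseudogenes (40.0%, against 3.04% of the other tested genes); in TPM 118 had a log2 fold of at least 3 and 2 one under 1. The median fold, signed as in the counts, was still 4.48 on the log2 scale of TPM plus 0.1. This argues against reads shared between near-identical copies as the cause for all of the set. The median covers pseudogenes and other genes together, so it cannot decide for the 62 pseudogenes. Shared reads stay open for these and for other single genes. A DNA segment around Omp is argued against too, with 0 of the 155 genes within 10 Mb of it (one-sided Fisher's exact p = 1). DNA that differs between the lines in blocks may account for part: the 11 receptors in the set (8 higher and 3 lower in mature neurons) formed 4 neighbouring pairs, but all of them in the 1 run of receptors that had prompted the test, with 0 pairs among the 6 others, so this stays open. The run is Olfr1045 to Olfr1049 on chromosome 2, 86195910 to 86258328 (GRCm38), where progenitors had 45, 16, 2, 4 and 0 counts in all while the next receptor on either side, Olfr52 and Olfr1051, had 861 and 103; genes of the set that differ by cell type, such as Neurog1, remain an untested biological part.

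The tested genes next to Neurog1 were higher in the progenitor libraries than in the mature neuron libraries. Within 100 kb of Neurog1 all 3 other tested genes were called higher in progenitors (3 of 3), with log2 folds between -9.09 and -6.42, while the 6 tested genes from there to 500 kb lay between -1.60 and 1.72, with 3 of them called higher in progenitors. Of these neighbours 4930550C17Rik and Gm17878 were weakly expressed, at means of 2.68 and 0.506 CPM in progenitors and 0 CPM in mature neurons. Their folds are therefore uncertain in size. Cxcl14 stood at 61.1 and 0.709 CPM. Extra copies of the DNA around Neurog1 in the progenitor line could give such a pattern. Regulation shared by neighbours in progenitor cells would give it as well and stays open.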

How the results depend on the processing

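The P16 and the P3 and P7 exclusions were chosen after seeing the data. The numbers of genes called between the populations stayed within 1.5 times under the alternatives run, from 4584 to 5323 higher and from 4781 to 5449 lower with 1 library left out. The age trend did not keep its count of 0: no low-count filter gave 315 rising and 455 falling genes, DESeq2 651 and 873, linear age 474 and 711, and leaving out 1 library from 0 to 367 and from 0 to 619. The difference of slopes gave 8 and 2 genes with DESeq2, and from 0 to 1 and from 0 to 2 with 1 library left out. With an estimated correlation 0 lists were called in any comparison. With fry 8 lists were higher and 10 lower in mature neurons, 0 rose and 2 fell with age, and 0 and 0 differed in slope. With 1 library left out, from 8 to 9 and from 7 to 9 lists differed between the populations, from 7 to 9 rose and from 10 to 13 fell with age, and from 2 to 8 and from 4 to 7 differed in slope. The receptor share kept its difference of 0.817 percentage points, from 0.782 to 0.84 with 1 library left out, but lost its call there, because so few splits cannot reach 0.05. The difference in receptors detected, 3.92, changed sign at 10 counts (-20.3), after thinning (-19.8), at 1 TPM (-8.67) and with libraries left out (from -1.75 to 13.2).

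Signs changed for Olfr536 (-0.45 without the P16 mature neuron library and up to 0.79 without another, -0.33 without both P16 libraries) and Olfr1507 (-0.09 without both). Without both P16 libraries the age direction turned for immature neuron (adjusted p = 0.962), sustentacular (0.962), Bowman gland (0.127), leukocyte (0.0374) and heat shock genes (0.298). For slope differences it turned for immature neuron (0.276, with a range from 6.52e-07 to 0.305 with 1 library left out) and cholesterol genes (0.0451, from 4.12e-11 to 0.195) without the P16 mature neurons, chromatin genes (0.719, from 0.000483 to 0.719) without the P2 mature neurons and ribosomal genes (0.27, from 0.00109 to 0.27) without the P3 progenitors. The cause was not tested. On log2(TPM + 0.1) the median of all genes moved to -0.12. Without the P3 and P7 progenitors 7834 genes were called between the populations, where fewer libraries entered the test. No paired analysis was possible by replicate number because these numbers only follow the order of the samples. With age as a block over P7 and P16, 9331 genes were called between the populations, 50.6% of them higher in mature neurons. In the simulated counts, where far fewer genes changed than were called here, 28.6% of 1.5-fold changes between populations were recovered. The share of such changes missed in the real comparison was not tested. Neither depth nor the number of libraries was varied in the simulation, so it cannot say which of them limits recovery.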

Other observations

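The values below were chosen after they were seen, and no explanation was tested for them.

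Olfr24 stood at 39.9 CPM in progenitors and 3.84 CPM in mature neurons (log2 fold -3.37, edgeR adjusted p = 0.000105). Gucy2d, the guanylyl cyclase of a non-canonical class of olfactory neurons, stood at 14.8 CPM in mature neurons and 1.9 CPM in progenitors (log2 fold 2.95, adjusted p = 9.7e-05), and Car2, a carbonic anhydrase, at 185 and 39.9 CPM (2.21, 0.000151). Vcp rose in mature neurons (log2 fold 2.47) while Vcp-rs fell (-6.31).

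Obp1a, an odorant-binding protein of nasal glands, reached 787 CPM in the P16 mature neurons against 2.57 CPM at P2 and 0.512 CPM at P7, and 45.3 CPM in the P16 progenitors. S100a8 and S100a9, proteins of neutrophils, stood at 36.3 and 55.3 CPM in the P16 mature neurons and at no more than 5.44 CPM in each other library. The heat shock gene Hspa1a stood at 92.3 CPM in that library and 14.8 CPM at P7, and Fos at 410 and 806 CPM.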
